A study of Mus musculus with 24 samples.

How the data were processed

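Total RNA from 12 mouse primary muscle cell cultures was labelled with biotin as cRNA and hybridised to Affymetrix MOE430A and MOE430B arrays, 1 of each type per culture, 24 arrays in all. The cultures, lettered A to L, formed 4 groups of 3: wild-type myoblasts (A to C), Rb-null myoblasts (D to F), wild-type myotubes (G to I) and MCK-cre Rb-flox myotubes (J to L). The labels call the myoblast cultures biological triplicates and place the myotube cultures in 3 independent cell lines per genotype. No letter occurs in more than 1 group, so no pairing was used. The p-values of single genes and of the permutation tests measure the spread between cultures. Those of the main gene list test set a list against the other genes and rest in part on the spread among genes. The number of arrays, 3 cultures per group, limits the precision of every value.

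The deposited tables hold 1 intensity per probe set and array, on a linear scale. The submitters' processing notes name MAS5 as the software and give no version. The scaling was read from the values: on every array the mean left after removing the lowest and highest 2% of probe sets is 1500. No detection calls were used. The record that the scanner software wrote for each array was read only for the day of the scan, the fluidics protocol and the chip type. On MOE430A, 5 myoblast cultures (A, C, D, E and F) were scanned on day 1, and culture B was scanned with all 6 myotube cultures on day 2. On MOE430B, A, C and D were scanned on day 1, E and F on day 2, and B with all 6 myotube cultures on day 3.

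Probe sets were assigned to genes with the supplied chip annotation and current gene names from RefSeq on mouse assembly GRCm38.p6, which was also used to place genes on chromosomes. Of 22690 probe sets on MOE430A, 20380 had 1 gene, 691 had several, 1555 had none and 64 were controls. Of 22575 on MOE430B, 14661 had 1 gene, 245 had several, 7605 had none and 64 were controls. Intensities were logged as log2(signal + offset), with the 20th percentile of each chip type's table as offset (130 for MOE430A and 206 for MOE430B). The offset understates the change of genes whose signal is near or below it in either group. A probe set was kept when its signal exceeded the 40th percentile of its own array on at least 3 of 12 arrays. Each gene was represented by 1 probe set: MOE430A before MOE430B, probe sets ending in _x_at or _s_at only where the gene had no other, then the highest mean. This left 14331 genes, 9143 from MOE430A and 5188 from MOE430B, and a gene was compared only within its own chip type.

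limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) fitted all 12 cultures with 1 mean per group. Benjamini-Hochberg adjustment ran over all genes tested, and a gene was called at an adjusted p under 0.05. The contrasts were wild-type myotube against wild-type myoblast, Rb-null against wild-type myoblast, MCK-cre Rb-flox against wild-type myotube, MCK-cre Rb-flox myotube against Rb-null myoblast, and the difference between both Rb effects. Fold changes are differences of group means on the log2 scale, with the standard error (SE) of the fit. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.

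The groups, contrasts, filters, named genes, gene lists and alternative settings were fixed before the data were examined. Named genes were, per main comparison and for the difference of the Rb effects, the 8 largest rises and 8 largest falls among called genes (for the main comparisons with no overlap between the cultures of both groups), a panel of 31 genes whatever their result, and up to 4 called members of each list, 2 from each end. The 20 lists were G1/S and DNA replication; G2/M and mitosis; pocket proteins, E2F family, cyclins and CDK inhibitors; sarcomere; calcium handling and neuromuscular junction; muscle energy metabolism; myogenic regulators; myoblast fusion and adhesion; satellite cell and activation; Notch pathway; p53 targets and apoptosis; autophagy; mitochondrial respiration; ribosome biogenesis; interferon response; and markers of fibroblasts, macrophages, endothelium, adipocytes and smooth muscle. Of 477 distinct listed genes, 19 had no probe set of their own in the chip tables and were not analysed here. Some lists share members, such as E2f1, Ccne1 and Ccne2 in G1/S and in the E2F and cyclin list, so they are not fully separate results. Lists were tested against the other genes with limma camera at a preset correlation between genes of 0.01, adjusted over the 20 lists within a comparison. An estimated correlation and limma fry were the alternatives. Called members were also counted with p adjusted over the list alone.

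Ratios of 3' to 5' signal of the Gapdh and beta-actin control probe sets and array medians were compared with exact 2-sided permutation tests of 3 against 3 cultures, which cannot give a p under 0.1. They formed a family of 24 tests. The geometric mean signals of the 18S rRNA and hybridisation spike-in probe sets were compared between scan days.

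Alternatives were quantile normalisation, median centring, other offsets (1, and the 40th percentile), no filter, a filter at the 60th percentile, eBayes without trend or per chip type, array weights, only the compared groups in the fit, the mean of a gene's probe sets, MOE430B before MOE430A, probe sets in place of genes, a fold threshold of 2, scan day as a fixed block (fitted per chip type, since the days differ), and leaving out each culture in turn. Fits on the last or the first scan day alone were added after the scan records were read. With the block, Rb-null against wild-type myoblasts rests on D, E and F against A and C on MOE430A. On MOE430B every contrast with Rb-null myoblasts then rests on D as their only culture. The fit and the list test were tested on simulated data that had the means and spread of the 14331 genes. With 200 genes changed between Rb-null and wild-type myoblasts, 0% were recovered at a log2 change of 0.6, 19.0% at 1, 78.0% at 2 and 97.5% at 3. A list shifted by 0.5 was recovered in 100% of 50 draws, and 1 of 900 unchanged lists was called. The simulated genes varied independently, unlike real ones, so the share of false list calls is a lower limit. On the 100 probe sets present on both chip types, the log2 changes correlated across probe sets, which are not independent replicates, at r = 0.898, 0.698 and 0.871 in the first 3 contrasts. The median absolute difference of the log2 changes between both chip types was 0.426, 0.161 and 0.177 in the same order.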

Results

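Gene expression was measured in mouse primary muscle cells before and after differentiation, with and without the retinoblastoma protein (Rb), which holds back E2F transcription factors and so the entry into S phase. Myoblasts, the proliferating precursors derived from satellite cells, grew in 20% serum with bFGF. Myotubes were harvested at day 6 in 5% horse serum. In the MCK-cre Rb-flox cultures a Cre recombinase under the muscle creatine kinase promoter, which is active once muscle cells differentiate, deletes floxed Rb. The Rb-null myoblasts lacked Rb while dividing, and their labels describe them as unable to differentiate normally. Each of the 4 groups had 3 cultures, with a purity of 99 to 100% given in the labels and fibroblasts named as the possible contaminant. Precision is limited by the 3 cultures per group.

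The median array signal of the groups lay between 604 and 717 on MOE430A and between 787 and 942 on MOE430B. Log2 values of replicate cultures correlated across genes at r = 0.885 to 0.959 in wild-type myoblasts, 0.927 to 0.944 in Rb-null myoblasts, 0.890 to 0.914 in wild-type myotubes and 0.852 to 0.910 in MCK-cre Rb-flox myotubes. The median SD of a gene between replicate cultures was 0.29, 0.25, 0.28 and 0.31 on the log2 scale in the same order. All 6 myotube cultures and wild-type myoblast culture B were scanned on the last day, and the other 5 myoblast cultures earlier. On MOE430A the 18S rRNA probe sets read 8403 ± 2440 (SD, 7 arrays) on the last day and 311 ± 119 (SD, 5 arrays) before, a ratio of 27.0. The hybridisation spike-ins differed 4.87-fold. On MOE430B the ratios were 21.2 and 3.86. The 3' to 5' ratio of beta-actin on MOE430A was 1.10 ± 0.0626 (SD) in wild-type myoblasts, 1.02 ± 0.0534 in Rb-null myoblasts, 0.533 ± 0.0962 in wild-type myotubes and 0.879 ± 0.0794 in MCK-cre Rb-flox myotubes. The wild-type myotube value differed from the wild-type myoblast and the MCK-cre Rb-flox value with an exact permutation p of 0.1 each, the smallest that 3 against 3 allows (0.267 adjusted over 24 tests). Against Rb-null myoblasts the MCK-cre Rb-flox ratio was lower by 0.145, and the array medians were higher by 114 (MOE430A) and 131 (MOE430B). Each of these also had an exact permutation p of 0.1. The Gapdh ratio of the groups ranged from 0.785 to 0.834.

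**Figure D1:**
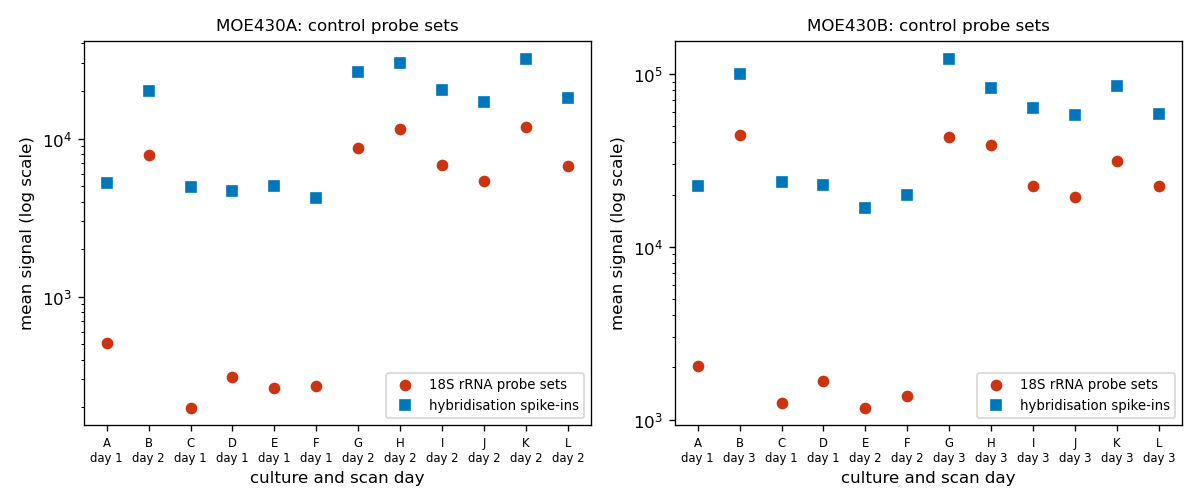
Geometric mean signal (log axis) of the 18S rRNA and hybridisation spike-in probe sets on each array, by culture and scan day, for MOE430A (left) and MOE430B (right); each point is 1 array. The 7 arrays of the last day lie above the 5 earlier ones on both chip types, with an 18S ratio of 27.0 and 21.2.

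Rb1 itself was measured first as a check of the labels. Its probe set on MOE430A read 1966 ± 794 (SD, n = 3) in wild-type and 466 ± 229 in Rb-null myoblasts, and 3414 ± 218 in wild-type and 692 ± 106 in MCK-cre Rb-flox myotubes. The signal was 3.53-fold lower in Rb-null myoblasts (log2 change -1.82, SE 0.31), with all 3 cultures below all 3 wild-type ones, but did not pass the limma test over all probe sets (adjusted p = 0.424, and 0.152 among genes). In MCK-cre Rb-flox myotubes Rb1 fell 4.33-fold (log2 change -2.11, SE 0.31, adjusted p = 0.00169 over all probe sets). A probe set outside the deleted part of the gene would not report the deletion, and its position relative to that part was not known. The other Rb1 probe set, on MOE430B, had group means of 28.8 to 49.5 and failed the filter.

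**Figure D2:**
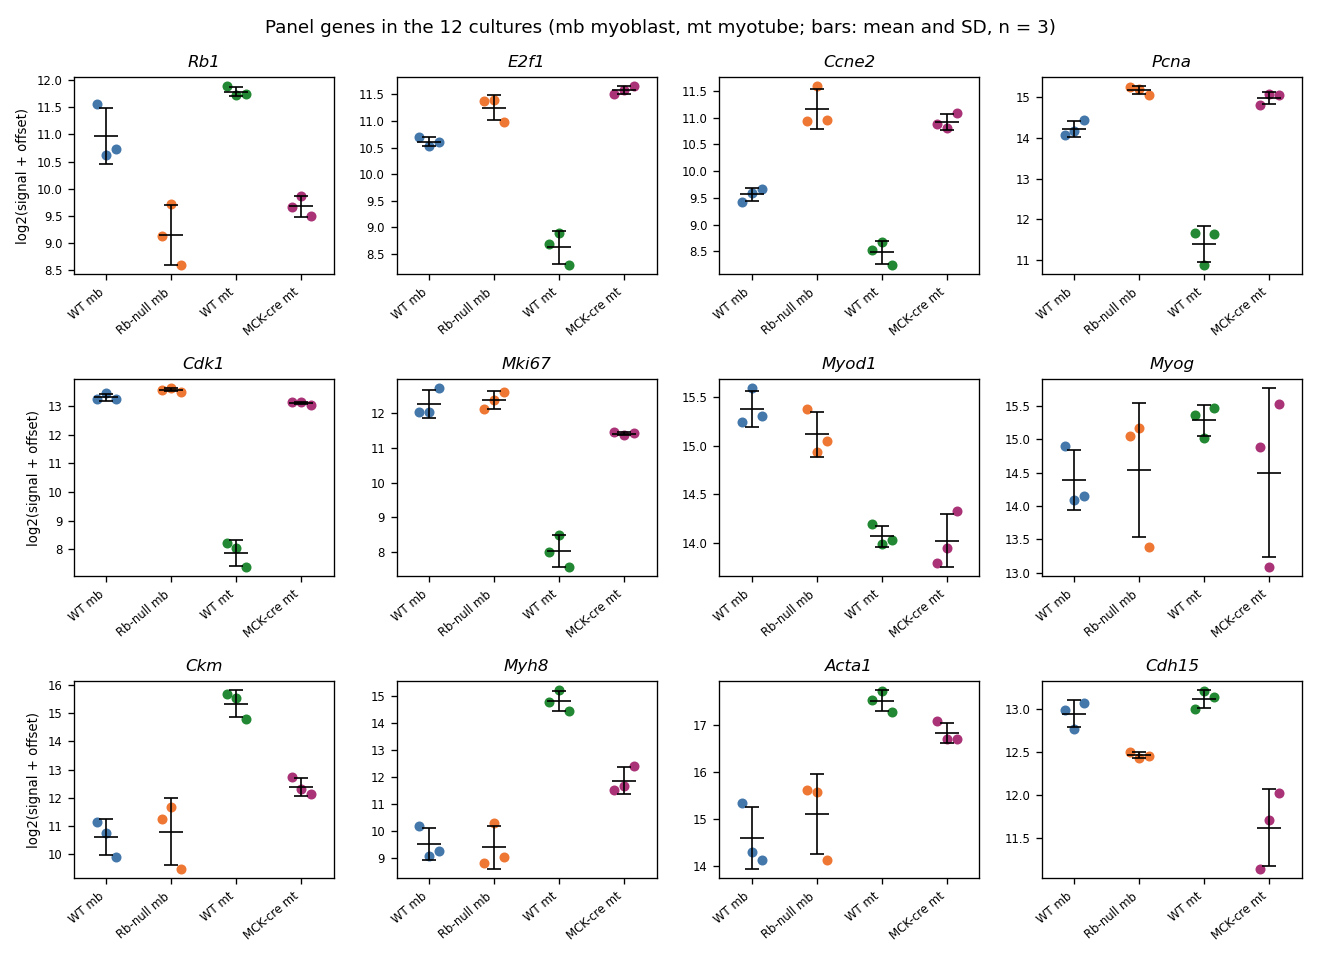
Log2(signal + offset) of 12 panel genes in the 4 groups (WT, wild-type; mb, myoblast; mt, myotube); points are cultures and bars show the mean and SD, n = 3. Cell-cycle genes such as Cdk1 were lowest in wild-type myotubes, and Ckm and Myh8 were highest there.

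The comparison of wild-type myotubes with wild-type myoblasts asked what differentiation does when Rb is present. Genes of the contractile apparatus and of calcium handling rose, and genes of DNA replication and mitosis fell. Trdn, which encodes triadin of the calcium release complex, rose 143-fold (log2 change 7.16, SE 0.28, n = 3 per group, limma adjusted p = 5.86e-09). Myh2, a fast myosin heavy chain, rose 101-fold (SE 0.60 log2), Sln, the calcium pump regulator sarcolipin, 80.7-fold (SE 0.63) and Tnni2, fast troponin I, 55.0-fold (SE 0.60). Cdk1, the kinase that drives mitosis, fell 43.0-fold (log2 change -5.43, SE 0.20) and Mcm6, a subunit of the replicative helicase, 27.1-fold (log2 change -4.76, SE 0.25). Other large falls were Sct (secretin, 70.9-fold), Mest (42.6-fold), Ube2c, which marks mitotic proteins for breakdown (34.8-fold), Birc5 (survivin, 26.0-fold), Cks2 (20.1-fold) and the proliferation marker Mki67 (18.7-fold). Ankrd23 (114-fold), Lmcd1 (54.8-fold), the perinatal myosin Myh8 (40.1-fold) and Tceal7 (38.1-fold) completed the largest rises.

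By list, 40 of 41 measured sarcomere genes rose and 0 fell (40 adjusted over the list alone), with a median log2 change of 3.56. Myh2 and Tnni2 rose most. Tpm1, tropomyosin, was among those that rose least (2.87-fold, adjusted p = 0.115 with scan day as a block), and the mean of its probe sets gave a log2 change of -1.20. The camera test gave an adjusted p of 1.88e-22, and adjusted p = 0.0530 with an estimated correlation. In calcium handling and the neuromuscular junction 17 of 24 rose and 0 fell (19 adjusted over the list alone, median 1.86, adjusted p = 3.22e-11, and adjusted p = 0.0570 with an estimated correlation). Of 17 muscle energy genes 16 rose (16 adjusted over the list alone, median 3.34, adjusted p = 3.30e-12, and adjusted p = 0.0437 with an estimated correlation). They include Ckm, muscle creatine kinase (26.8-fold), and Mb, myoglobin (25.4-fold). Alongside these lists the beta-actin 3' to 5' ratio was lower in wild-type myotubes (0.533 against 1.10), and the 18S signal was higher on the days on which myotubes were scanned.

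G1/S and DNA replication genes fell in 40 of 49 cases and rose in 0 (41 adjusted over the list alone, median -1.81, camera adjusted p = 6.63e-26, and adjusted p = 0.00485 with an estimated correlation). G2/M and mitosis genes fell in 45 of 46 cases (46 adjusted over the list alone, median -2.89, adjusted p = 3.04e-38, and adjusted p = 0.00485 with an estimated correlation). Ribosome biogenesis genes fell in 13 of 24 cases, among them Rrs1 (5.43-fold) and Npm1, nucleophosmin (4.16-fold), and 0 rose (14 adjusted over the list alone, median -0.64, adjusted p = 7.17e-07, and adjusted p = 0.0530 with an estimated correlation). Of the 28 pocket protein, E2F, cyclin and CDK inhibitor genes 10 fell and 3 rose (13 and 4 adjusted over the list alone, adjusted p = 0.00101, and adjusted p = 0.0530 with an estimated correlation). E2f1 fell 3.97-fold (SE 0.21), Ccne1 (cyclin E1) 5.13-fold (SE 0.32) and Cdk6 5.84-fold (SE 0.29), while Cdkn1a, the CDK inhibitor p21, rose 3.63-fold (SE 0.21) and the pocket protein gene Rbl2 1.78-fold (SE 0.26, adjusted p = 0.216 with scan day as a block).

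Myogenic regulators split: 4 rose and 8 fell of 17 (4 and 8 adjusted over the list alone, camera adjusted p = 0.0767). Mef2c rose 20.9-fold (SE 0.47) and Myf6 8.30-fold (SE 0.52), and the differentiation inhibitors Id1, Id2 and Id3 fell 5.88-fold, 14.7-fold and 11.2-fold. Myod1 fell 2.47-fold (SE 0.20), while Myog had a log2 change of 0.90 (SE 0.56) that was not called. Myog was already bright in the wild-type myoblasts, with signals of 30530 in A, 17380 in B and 18080 in C. Among fusion and adhesion genes 8 of 20 rose and 6 fell (adjusted p = 0.462); Mymk, the fusogen myomaker, rose 4.97-fold and Vcam1 fell 4.79-fold. Satellite cell genes (2 rose and 6 fell of 13, adjusted p = 0.0894) and Notch pathway genes (0 rose and 5 fell of 13, adjusted p = 0.152, and 0.0313 without a filter) were not called as lists; Pax7 fell 3.02-fold and Notch2 4.21-fold. In autophagy 6 of 17 rose and 0 fell (adjusted p = 0.190, and 0.00791 with scan day as a block), and p53 targets had 3 rises and 4 falls of 21 (adjusted p = 0.684, with a median of 0.07 and a mean of -0.04).

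Mitochondrial respiration (6 rose and 1 fell of 26, adjusted p = 0.0354) and smooth muscle markers (3 rose of 5, among them Des, desmin, adjusted p = 0.0472) were called by camera, with adjusted p = 0.501 and adjusted p = 0.172 with an estimated correlation. Both calls ended with quantile normalisation (0.0535 each), and the mitochondrial one also with scan day as a block (0.0917). Interferon genes had 1 rise and 2 falls of 19 (adjusted p = 0.943; the median was 0.26 and the mean 0.02, while camera pointed down). Fibroblast and matrix genes had 3 rises and 6 falls of 22 (adjusted p = 0.462), a median of 0.43 and a mean of -0.26; Col3a1, a fibrillar collagen, fell 16.5-fold and Col5a2 4.45-fold. Macrophage (1 rise of 6, adjusted p = 0.184), endothelial (0 of 5, adjusted p = 0.462) and adipocyte markers (1 rise and 1 fall of 5, adjusted p = 0.943, median 0.50, camera pointing down) were not called.

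In all, 4267 of 14331 genes were called, 2072 higher and 2195 lower in myotubes, 1238 and 1436 of them at least 2-fold. Groups did not overlap for 44.1% of genes, where chance gives 10%. Leaving out 1 culture gave 2814 (without C) to 4926 genes (without B). The median change of all genes was 0.14, and median centring moved it to 0.02 and the split to 1589 higher and 2454 lower (39.3% higher in place of 48.6%). With scan day as a block, which rests on culture B as the only myoblast culture of the last day, 2108 genes were called (1039 higher and 1069 lower), 1910 of them shared with the pooled fit. Within the last scan day culture B alone stood against the 3 wild-type myotube cultures. The myoblast side had no spread of its own there, so only list medians are given here. These arrays are part of the pooled fit, so the medians are no separate check on the scan day. List medians with the block and within the last day were -1.70 for G1/S, -2.80 for G2/M, 3.92 for the sarcomere, 1.86 for calcium handling, 3.40 for muscle energy and -0.72 for ribosome biogenesis. Fusion and adhesion (0.008), p53 (0.003), interferon (0.06), fibroblast (-0.04), endothelial (-0.37) and adipocyte medians (-0.27) moved to or past 0.

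Rb-null against wild-type myoblasts asked what the loss of Rb does in dividing precursors. No single gene passed the test, but G1/S and DNA replication genes stood higher as a group: all 49 measured members had a positive change, with a median of 0.59 on the log2 scale. The camera adjusted p was 3.84e-36, and adjusted p = 0.00163 with an estimated correlation. Adjusted over the list alone, 23 of the 49 were higher and 0 lower. Ccne2, cyclin E2, had the smallest adjusted p of all genes (3.02-fold higher, log2 change 1.59, SE 0.24, n = 3 per group, limma adjusted p = 0.0934). Pcna, the sliding clamp of DNA polymerase, was 1.92-fold higher (SE 0.22, adjusted p = 0.367), Mcm5 1.78-fold (SE 0.20, adjusted p = 0.367) and E2f1 1.56-fold (SE 0.21, adjusted p = 0.667).

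G2/M genes were positive in 40 of 46 cases, with a smaller median of 0.25 (0 called, 0 adjusted over the list alone, camera adjusted p = 1.66e-06, and adjusted p = 0.234 with an estimated correlation). Mki67 (log2 change 0.12, SE 0.26) and Top2a (0.20, SE 0.17) were not called. The pocket protein, E2F and cyclin list (median 0.26, adjusted p = 0.000130, and adjusted p = 0.0618 with an estimated correlation) had 8 members higher and 2 lower adjusted over the list alone. For p53 targets the median was 0.22 (adjusted p = 0.000109, and adjusted p = 0.0793 with an estimated correlation; 4 higher adjusted over the list alone), and for ribosome biogenesis 0.17, with 22 of 24 positive (adjusted p = 0.00150, and adjusted p = 0.234 with an estimated correlation). Fibroblast and matrix genes were lower as a list (median -0.23, adjusted p = 0.0260, and adjusted p = 0.234 with an estimated correlation), a call that ended with scan day as a block (0.0611).

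Muscle lists were not called in Rb-null myoblasts, with an exception for the sarcomere under 2 other settings. The camera adjusted p was 0.0599 for the sarcomere (median 0.18; 0.0310 with quantile normalisation and 0.0264 without a filter), 0.683 for calcium handling (median -0.01), 0.831 for muscle energy (-0.04), 0.665 for myogenic regulators (-0.16) and 0.665 for fusion and adhesion (-0.06). Myod1 had a log2 change of -0.26 (SE 0.20), Myog 0.15 (SE 0.56) and Cdh15, M-cadherin, -0.48 (SE 0.20), none of them called. Satellite cell (adjusted p = 0.210), Notch (0.642), autophagy (0.0955), mitochondrial (0.642), interferon (0.642), macrophage (0.665), endothelial (0.665), adipocyte (0.642) and smooth muscle lists (0.599) were not called either. With scan day as a block the satellite cell list (median -0.22, adjusted p = 0.0259) and the autophagy list (median -0.21, adjusted p = 0.000780) were called lower. Their measured members were all on MOE430A, where the block sets D, E and F against A and C, without B. The other genes in the list test include those of MOE430B, where the block rests on D alone against A and C. The macrophage median (0.07) and mean (-0.07) differed in sign, as did those of calcium handling (-0.01 and 0.02).

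limma called 0 of 14331 genes here, with 751 at an unadjusted p under 0.05 where chance gives 717. Groups did not overlap for 12.1% of genes (10% by chance). Fits per chip type called 2 genes and array weights 7. Scan day as a block gave 0 calls (732 unadjusted). Within the first scan day on MOE430A 0 were called (3 Rb-null against 2 wild-type cultures, 869 of 9143 unadjusted where chance gives 457). On MOE430B that day held 1 Rb-null against 2 wild-type cultures, so no count is given there. The G1/S median was 0.65 with the block and 0.66 within the first day on MOE430A (45 genes), and the G2/M median 0.26 and 0.25 (44 genes). The block likewise sets D, E and F against A and C on MOE430A, and D alone against A and C on MOE430B. The block and the first day are therefore not separate checks.

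MCK-cre Rb-flox against wild-type myotubes asked what the deletion of Rb does at the end of differentiation. Cell-cycle genes rose, a part of the contractile and energy genes fell, and MHC class I and interferon genes rose. Cdk1 rose 37.3-fold (log2 change 5.22, SE 0.20, n = 3 per group, limma adjusted p = 8.64e-09), from a signal of 113 ± 69.1 (SD) to 8678 ± 303. The helicase genes Mcm6, Mcm3 and Mcm2 rose 31.7-fold (SE 0.25), 19.7-fold (SE 0.24) and 14.6-fold (SE 0.15), Ube2c 17.7-fold (SE 0.19) and Topbp1, a replication checkpoint gene, 16.0-fold (SE 0.23). The probe sets of Topbp1 disagreed: the difference between both Rb effects was 3.58 with this one and -0.16 with the one on MOE430B. Lpl, lipoprotein lipase, rose 15.9-fold (SE 0.36) and H2-D1, an MHC class I heavy chain, 13.8-fold (SE 0.93, adjusted p = 0.0174). Myh2 fell 57.3-fold (log2 change -5.84, SE 0.60), Car3, carbonic anhydrase 3, 41.0-fold (SE 0.38) and Sln 22.0-fold (SE 0.63). Ablim3 (16.4-fold), Ramp1 (13.2-fold), Cilp (11.8-fold), Cdc42ep2 (11.5-fold) and the fatty acid transporter Cd36 (11.5-fold) also fell.

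Of 49 G1/S and DNA replication genes 42 rose and 0 fell (46 adjusted over the list alone, median 2.22, camera adjusted p = 8.19e-49, and adjusted p = 0.000543 with an estimated correlation). Of 46 G2/M and mitosis genes 38 rose and 0 fell (43 adjusted over the list alone, median 1.92, adjusted p = 1.03e-41, and adjusted p = 0.00371 with an estimated correlation). Pcna rose 11.9-fold (SE 0.22), Top2a 11.9-fold (SE 0.17), Mki67 10.4-fold (SE 0.26), and Plk1 and Aurkb, mitotic kinases, 2.05-fold (SE 0.23) and 2.07-fold (SE 0.24). In the pocket protein, E2F and cyclin list 11 rose and 2 fell of 28 (12 and 4 adjusted over the list alone, adjusted p = 0.000412, and adjusted p = 0.0605 with an estimated correlation). Ccne1 rose 12.3-fold, E2f1 7.77-fold, Ccne2 5.43-fold and the pocket protein p107 gene Rbl1 3.74-fold, while Ccnd3, cyclin D3, fell 2.08-fold. Ccne1, E2f1 and Ccne2 are also members of the G1/S list. Cdkn1a had a log2 change of -0.56 (SE 0.21) that was not called.

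Of 41 sarcomere genes 13 fell and 0 rose (21 lower adjusted over the list alone, median -1.28, camera adjusted p = 3.23e-14, and adjusted p = 0.118 with an estimated correlation). Tcap, telethonin, fell 9.05-fold (SE 0.35) and Myh8 7.79-fold (SE 0.40), whereas Acta1, skeletal actin (log2 change -0.69, SE 0.40), Myh3 (-1.09, SE 0.58) and Tnnt3 (-1.28, SE 0.64) were not called. In calcium handling 6 of 24 fell (8 adjusted over the list alone, median -0.73, adjusted p = 1.37e-07, and adjusted p = 0.121 with an estimated correlation), with Casq1, calsequestrin, down 5.68-fold. Of 17 muscle energy genes 11 fell (12 adjusted over the list alone, median -1.28, adjusted p = 4.88e-09, and adjusted p = 0.0605 with an estimated correlation), among them Ckm (7.79-fold) and Ampd1 (6.13-fold). In mitochondrial respiration 4 of 26 fell (7 adjusted over the list alone, adjusted p = 3.25e-06, and adjusted p = 0.184 with an estimated correlation), including Sdhc and Uqcrc2 (1.80-fold and 1.77-fold). The beta-actin 3' to 5' ratio moved with these lists, 0.879 in MCK-cre Rb-flox and 0.533 in wild-type myotubes.

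Myogenic regulators had 2 rises and 3 falls of 17 (adjusted p = 0.779): Myf6 fell 5.32-fold and Mef2c 3.38-fold, Id2 rose 2.69-fold and the cofactor gene Eya1 2.46-fold, and Myod1 (log2 change -0.05, SE 0.20) and Myog (-0.79, SE 0.56) were not called. Fusion and adhesion genes had 2 rises and 3 falls of 20 (adjusted p = 0.387), with Cdh15 falling 2.82-fold (SE 0.20). p53 targets and apoptosis genes rose in 8 of 21 cases and fell in 0 (11 and 1 adjusted over the list alone, median 0.81, adjusted p = 5.47e-05, and adjusted p = 0.0605 with an estimated correlation). Apaf1, the core of the apoptosome, rose 3.02-fold (SE 0.23), and the BH3-only genes Pmaip1 and Bcl2l11 3.00-fold (SE 0.43) and 1.93-fold (SE 0.22). Autophagy (1 rise and 3 falls of 17, adjusted p = 0.104), ribosome biogenesis (2 rises of 24, adjusted p = 0.563), satellite cell (3 rises of 13, adjusted p = 0.0943) and Notch lists (2 rises and 1 fall of 13, adjusted p = 0.779) were not called; Map1lc3b fell 1.99-fold, and Notch2 rose 2.38-fold.

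Interferon response genes, which here include MHC class I, rose in 14 of 19 cases and fell in 0 (17 adjusted over the list alone, median 1.72, camera adjusted p = 1.16e-11, and adjusted p = 0.0956 with an estimated correlation). H2-K1 rose 10.4-fold (SE 0.72), Ddx58, the RNA sensor RIG-I, 2.56-fold (SE 0.25) and Irf7 2.37-fold (SE 0.35). The 3 cultures differed: the list median over the wild-type myotube mean was 2.00 in J, 0.90 in K and 2.08 in L, and H2-D1 read 24790, 2125 and 34810. Fibroblast and matrix genes had 5 rises and 1 fall of 22 (adjusted p = 0.0770), with Col3a1 (7.39-fold), Col5a2 (3.31-fold) and Fn1 (2.45-fold) higher and S100a4 3.38-fold lower. Adipocyte markers had 2 rises of 5, Lpl and Cebpa (adjusted p = 0.0772). Macrophage (0 of 6, adjusted p = 0.779), endothelial (0 of 5, adjusted p = 0.779) and smooth muscle markers (1 fall of 5, Smtn, adjusted p = 0.273, and 0.0466 without a filter) were not called.

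In all, 1643 genes were called, 1002 higher and 641 lower, 710 and 392 of them at least 2-fold. Groups did not overlap for 27.9% of genes (10% by chance). All 6 cultures were scanned on the last day, so list medians with the day block and within that day equalled the pooled ones to 2 decimals. The block gave 1854 calls (1574 shared with the pooled fit), the last day alone 1035 (604 higher and 431 lower, 990 shared), and a fit of these groups only 1020. On MOE430A, which held 9143 of the genes, all 3 wild-type myotube arrays had 1 fluidics protocol and all 3 MCK-cre Rb-flox arrays another, so protocol and genotype were confounded among the myotubes there; on MOE430B the protocol was mixed and 1 MCK-cre Rb-flox array (L) had no entry. Wild-type myoblast B and Rb-null F had the wild-type myotube protocol on MOE430A, with Cdk1 signals of 11040 and 11480.

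**Figure D3:**
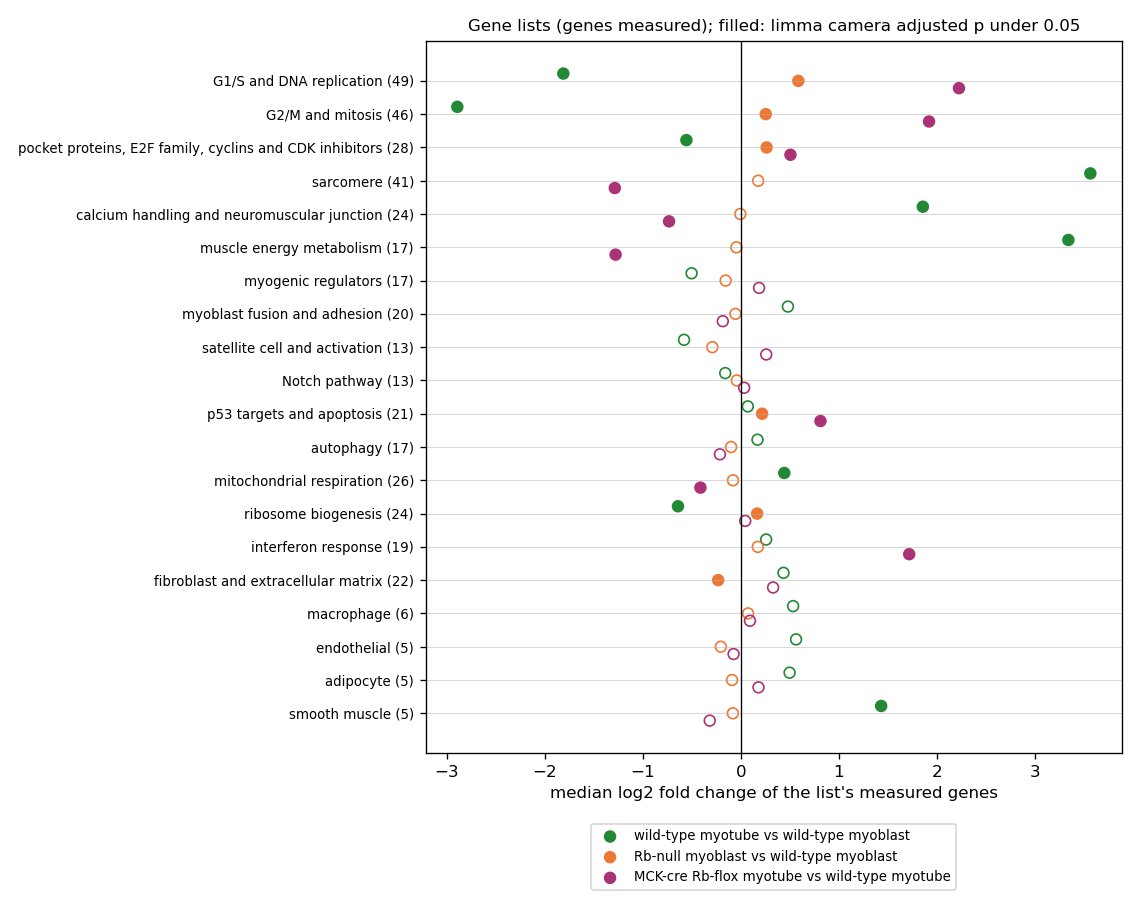
Median log2 fold change of the measured members of 20 gene lists (number of genes in brackets) in 3 comparisons; filled points have a limma camera adjusted p under 0.05. The G1/S median was -1.81 in wild-type differentiation, 0.59 in Rb-null myoblasts and 2.22 in MCK-cre Rb-flox myotubes.

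Whether the effect of Rb loss differed between myotubes and myoblasts was tested as the difference of both contrasts. Rb-null myoblasts and MCK-cre Rb-flox myotubes differ in how and when Rb was lost, and no group had Cre or floxed Rb alone. The difference therefore does not separate cell state from genotype or cell line. The change was larger in myotubes for Cdk1 (difference 4.96 on the log2 scale, SE 0.28, limma adjusted p = 2.57e-06), Mki67 (3.26, SE 0.37) and E2f1 (2.32, SE 0.30), and more negative for Myh2 (-5.12, SE 0.85) and Ckm (-3.16, SE 0.68). By list, 22 of 49 G1/S genes had a higher difference and 0 a lower one (36 and 1 adjusted over the list alone), with a median of 1.45 and adjusted p = 0.00237 with an estimated correlation. For G2/M it was 22 of 46 (36 adjusted over the list alone, median 1.58, adjusted p = 0.00515 with an estimated correlation). In all, 320 genes were called, 214 higher and 106 lower. With scan day as a block 278 were called, 224 of them shared. Array weights gave 723, and leaving out 1 myoblast culture gave 138 (without C), 155 (without E), 169 (without D), 236 (without B), 267 (without A) or 313 (without F). The p53 list was not called (adjusted p = 0.0550), but was with scan day as a block (0.0407) and with quantile normalisation (0.0325). Ccne2 (0.85, SE 0.34, adjusted p = 0.253) and Rb1 (-0.29, SE 0.43, adjusted p = 0.845) were not called.

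No gene was called in both Rb comparisons, as 0 were called in myoblasts, so no overlap test could be made. Per chip type 2 genes and with array weights 4 genes were called in the same direction in both. Across all 14331 genes the 2 changes, which share no arrays, correlated at r = 0.159 and rho = 0.146; genes are not independent replicates. Of the 1002 genes that rose in MCK-cre Rb-flox myotubes 715 (71.4%) had a positive change in Rb-null myoblasts, and of the 641 that fell 382 (59.6%) had a negative one, against 48.7% positive among all genes.

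MCK-cre Rb-flox myotubes against Rb-null myoblasts compared both Rb-deficient states, whose genotypes are not the same. Muscle genes stood higher in the myotubes and mitotic and ribosome biogenesis genes lower. Myh8 rose by 2.48 on the log2 scale (SE 0.40, n = 3 per group, limma adjusted p = 0.00168), Acta1 by 1.73 (SE 0.40) and Ckm by 1.58 (SE 0.48), while Mki67 changed by -0.96 (SE 0.26) and Myod1 by -1.09 (SE 0.20). Cdk1 (-0.46, SE 0.20, adjusted p = 0.121) and Pcna (-0.19, SE 0.22, adjusted p = 0.550) were not called. Of 41 sarcomere genes 24 rose and 0 fell (median 1.60, camera adjusted p = 9.70e-12), of 24 calcium handling genes 14 rose (median 1.0, adjusted p = 1.03e-07) and of 17 energy genes 13 (median 1.51, adjusted p = 3.09e-07); each had adjusted p = 0.136 with an estimated correlation. G2/M genes fell in 27 of 46 cases (median -0.96, adjusted p = 3.60e-19, and adjusted p = 0.0411 with an estimated correlation) and ribosome biogenesis genes in 15 of 24 (median -0.89, adjusted p = 3.65e-12, and adjusted p = 0.0411 with an estimated correlation). G1/S genes fell in 6 of 49 cases (median -0.25, adjusted p = 0.00334, and adjusted p = 0.186 with an estimated correlation). Interferon genes rose in 14 of 19 cases (median 1.91, adjusted p = 2.04e-08, and adjusted p = 0.136 with an estimated correlation). Adjusted over the list alone, 36 sarcomere, 17 calcium handling, 13 energy and 17 interferon genes rose, and 37 G2/M, 18 ribosome biogenesis and 5 G1/S genes fell. The pocket protein and cyclin list (1 rise and 6 falls of 28, median -0.26, adjusted p = 0.0292), myogenic regulators (2 rises and 6 falls of 17, median -0.04, adjusted p = 0.0313), adipocyte markers (2 rises of 5, adjusted p = 0.0313) and smooth muscle markers (2 rises of 5, adjusted p = 0.0292) were also called by camera. With an estimated correlation these had adjusted p = 0.136, adjusted p = 0.136, adjusted p = 0.186 and adjusted p = 0.136. Fusion (adjusted p = 0.833), satellite cell (0.333), Notch (0.212), p53 (0.166), autophagy (0.312), mitochondrial (0.333), fibroblast (0.131), macrophage (0.0596) and endothelial lists (0.333) were not called. The pocket protein (0.416), myogenic (0.468, with the median at 0.40) and adipocyte calls (0.0687) ended with scan day as a block, and autophagy was called (0.00174). The pocket protein call also ended with quantile normalisation (0.0844); without a filter the adipocyte (0.0933) and smooth muscle calls (0.0920) ended and the endothelial list was called (0.0345).

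In all, 2706 genes were called, 1373 higher and 1333 lower; groups did not overlap for 41.0% (10% by chance). Leaving out 1 culture gave 1543 (without D) to 3236 genes (without B), with 1729 without E. The median change of all genes was 0.16, and median centring moved it to -0.04 and the split to 735 higher and 1823 lower (28.7% higher in place of 50.7%). No scan day held both groups, and the 18S signal differed with them. The beta-actin 3' to 5' ratio on MOE430A was 0.879 in the myotubes and 1.02 in the myoblasts. With scan day as a block, which borrows the day difference from the wild-type myoblast cultures, 193 genes were called, 157 of them shared, and the medians were 2.18 for the sarcomere, -0.90 for G2/M, -1.07 for ribosome biogenesis and 1.75 for interferon genes. Single members called with the block were 3 of 41 sarcomere, 2 of 24 calcium handling, 2 of 17 energy, 7 of 46 G2/M, 3 of 24 ribosome biogenesis, 0 of 49 G1/S and 0 of 19 interferon genes.

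**Figure D4:**
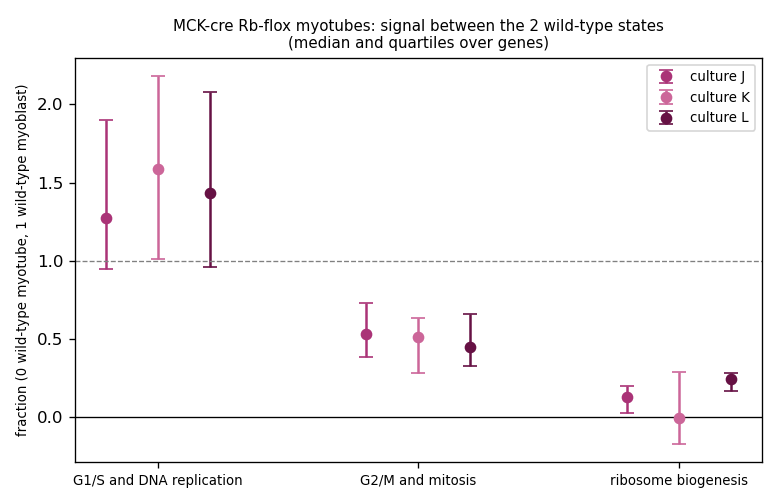
Position of each MCK-cre Rb-flox myotube culture between the wild-type myotube signal (0) and the wild-type myoblast signal (1) on the linear signal scale, for list genes that fell in wild-type differentiation; points are medians over genes and bars the quartiles. G1/S medians were 1.27 to 1.59, G2/M medians 0.449 to 0.528 and ribosome biogenesis medians -0.00623 to 0.239.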

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

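The simulation of small changes was planned before its result was seen; the other tests of explanations here, and the counts over other splits of the cultures, were chosen after the results were seen.

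The change from wild-type to Rb-deficient cells differed between myotubes and myoblasts by a test of the difference itself for 320 genes and 11 lists. The Rb-deficient genotypes were not the same, so cell state is not separated here from genotype or cell line. The median log2 difference was 1.45 for G1/S, 1.58 for G2/M, 0.29 for pocket proteins and cyclins, 0.52 for satellite cell, 1.85 for interferon, 0.42 for fibroblast and matrix, and 0.24 for adipocyte genes. It was -1.68 for the sarcomere, -0.60 for calcium handling, -1.09 for muscle energy and -0.46 for mitochondrial respiration. With an estimated correlation G1/S (adjusted p = 0.00237) and G2/M (adjusted p = 0.00515) stayed called and the other 9 did not: adjusted p = 0.166 for pocket proteins, calcium handling and satellite cell, 0.126 for the sarcomere, interferon and fibroblast lists, 0.116 for muscle energy, and 0.224 for mitochondrial and adipocyte genes. The adipocyte call also ended with scan day as a block (adjusted p = 0.0685), quantile normalisation (0.0581), an offset of 1 (0.0515) and no filter (0.212), which also ended the pocket protein (0.0512) and satellite cell calls (0.126). By limma fry the calcium handling (0.0563) and mitochondrial lists (0.0589) were not called.

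Among cell-cycle genes the difference on the log2 scale was 4.96 for Cdk1, 4.03 for Mcm6, 3.66 for Ube2c, 3.58 for Topbp1 (-0.16 with its MOE430B probe set), 3.38 for Top2a, 3.30 for Pole, 3.26 for Mki67, 2.93 for Ccne1, 2.63 for Pcna, 2.32 for E2f1, 2.15 for Mcm5, 1.58 for Hmmr, 1.57 for Ncapd2, 1.55 for Mcm7, 1.5 for Prim1 and 1.46 for Tfdp1. Among muscle genes it was -5.12 for Myh2, -4.38 for Sln, -3.95 for Ablim3, -3.87 for Tnni2, -3.84 for Tcap, -3.16 for Ckm, -2.84 for Myh8, -2.73 for Tnnc2, -2.49 for Cav3 and -2.45 for Ampd1. Interferon genes had 3.92 (Ifi202b), 2.92 (Ifi35), 2.54 (B2m) and 1.85 (Tap1), and matrix genes 2.03 (Ddr2), 1.82 (Col5a2) and 1.20 (Fbln1). Others were Lpl (4.69), Sct (4.26), Notch2 (1.70), Apaf1 (1.38), Itga4 (-1.94), Cilp (-3.79), Cd36 (-3.81) and Ramp1 (-4.65). With scan day as a block Ablim3 (adjusted p = 0.172), Tnni2 (0.0643), Cilp (0.197), Tfdp1 (0.0601), Tnnc2 (0.0968), Cav3 (0.0562), Ampd1 (0.124), Itga4 (0.0560), Apaf1 (0.0575) and B2m (0.0605) were no longer called. Of 100 splits of the cultures 12, the real one included, called at least as many genes as the real split (320). All 12 were among the 15 splits that kept the real myotube groups, and so carry the myotube difference with them. The highest other (847) kept the real myoblast groups too, with the myotube groups swapped. Such splits are no reference for chance, so this count can neither exclude nor show it. Among the 85 others the highest count was 1, which shows only that cultures G to I and J to L differed. Genotype, cell line and, on MOE430A, fluidics protocol are not told apart by it. Leaving out 1 myoblast culture gave 138 (C), 155 (E), 169 (D), 236 (B), 267 (A) or 313 (F), and array weights gave 723.

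The 18S rRNA and hybridisation spike-in probe sets, which no comparison used, differed with the scan day: 27.0-fold and 4.87-fold on MOE430A, and 21.2-fold and 3.86-fold on MOE430B. The last day held all myotubes and culture B.

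The cell-cycle genes were higher in MCK-cre Rb-flox than in wild-type myotubes, which could come from undifferentiated myoblasts, the fluidics protocol or fibroblasts. Myoblasts with the profile measured in 20% serum would return all genes that fell in differentiation by 1 fraction of the linear signal. G1/S genes, however, stood further back than ribosome biogenesis genes by a gap of at least 1.14 in each of the 3 cultures (G2/M genes by 0.401 in J, 0.52 in K and 0.21 in L). The 100 brightest other genes that fell at least 4-fold stood back by medians of 0.173, 0.194 and 0.137. These lay under the lower quartiles of the G2/M genes (0.381, 0.279 and 0.323, nearest in K at -0.085), as in all 8 gene sets tried (7 of 8 with culture B as the only reference). The sets share genes, and with all 288 other genes that fell at least 4-fold the margin in K was only -0.02. These values argue against wild-type myoblasts with that profile as the whole cause of either rise and leave a share open. For G2/M the margin was small in the larger sets. Undifferentiated myoblasts kept in 5% serum were not measured, with or without Rb, so the test does not cover them and they stay open. Measured towards Rb-null myoblasts the G2/M test failed in K (0.026) and held in 1 of 8 sets. Rb-deficient myoblasts therefore stay open for G2/M, while for G1/S the test held in all 8 sets. The protocol as the whole cause is argued against on MOE430A, where the rise had a median of 2.04 (lower quartile 1.25). The protocols differed there within a group by -0.02 (A and C against B, scanned on another day) and 0.002 (D and E against F). On MOE430B, under 1 protocol, J and K stood above H and I in 41 of 49 probe sets (median 0.837, with -0.004 for all probe sets). Each pair of cultures differed by at least 0.583, against 0.408 within a group, though K against H had a lower quartile of 0.067. The rule for these pairs was set after an earlier one had left the question open. They therefore show a difference under 1 protocol without settling the cause, and a share of the protocol stays open on both chip types. The 5 brightest fibroblast genes had a median change of 1.295, so fibroblasts stay open, although Fn1, Col5a2 and Col3a1 were also bright in wild-type myoblasts (23860, 17270 and 17910, against 28030, 13110 and 8316 in MCK-cre Rb-flox myotubes), S100a4 moved the other way (-1.76), and Col1a1 read 80.5 in K (Cdk1 8849) and 1541 in wild-type myotube G (Cdk1 169.5); the deletion of Rb, the biological explanation the design gives, remains open beside these.

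Interferon and MHC class I genes were higher in MCK-cre Rb-flox myotubes, less so in culture K, which might reflect a strain variant of the MHC region or macrophages. The 14 list members outside chromosome 17 had a median change of 1.556 with 9 called, which argues against a variant of that region as the whole cause. The macrophage list had a median of 0.093 with 0 of 6 called and dim signals (392.7 to 1478), which argues against macrophages; the other 8 markers of that list were under the signal filter. Lymphocytes, infection and genotype were not tested and stay open.

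No gene was called by limma in Rb-null myoblasts (751 at an unadjusted p under 0.05) while G1/S genes were higher as a list. Leaving out wild-type culture B, scanned with the myotubes, gave 0 genes (745 unadjusted), but that fit recovered only 11.5% of simulated genes at a change of 1 (77% at 2), so spread from culture B stays open. In simulated data 0% of genes changed by 0.6 on the log2 scale, near the list's median of 0.59, were recovered, so changes too small for 3 against 3 cultures may account for it.

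For each pairwise comparison 10 splits exist, so a share under 0.05 cannot be reached. In wild-type differentiation the real count was 4267 and the highest other 0, with 1 split as large. In MCK-cre Rb-flox against wild-type myotubes it was 1643 and 3, again 1 split, and against Rb-null myoblasts 2706 and 0, also 1. In Rb-null myoblasts the real count was 0 and the highest other 43 (A, D and E against B, C and F). With a real count of 0 all 10 splits are at least as large by definition, so this count tests nothing. In the other comparisons a split that mixes both groups adds their difference to the spread, which by itself lowers its count.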

How the results depend on the processing

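The fits within the last and the first scan day were chosen after seeing the data; the other alternatives were planned. Over the settings that kept all cultures, named genes kept direction and side of the threshold in 3569 cases, lost the call in 265, gained one in 15 and reversed in 6. List results did so in 515, 58, 27 and 0 cases. Where no reason is given, the cause was not tested.

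With an estimated correlation between genes, camera called 3, 1, 2, 2 and 2 of 20 lists in wild-type differentiation, Rb-null myoblasts, MCK-cre Rb-flox against wild-type myotubes, the same against Rb-null myoblasts, and the difference of the Rb effects, where the preset correlation called 9, 6, 9, 11 and 11. limma fry, which does not compare a list with other genes, called 15 in wild-type differentiation, 2 in Rb-null myoblasts and 17 between the Rb-deficient states.

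Array weights called 6432 genes in wild-type differentiation, 7 in Rb-null myoblasts and 723 for the difference of the Rb effects, with 4 shared between both Rb effects. eBayes per chip type called 2 in Rb-null myoblasts, with 2 shared. A fit of the compared groups only called 1020 between the myotubes, with fewer samples behind the spread. Scan day as a block called 2108 in wild-type differentiation and 193 between the Rb-deficient states, where myoblasts and myotubes share a day through culture B alone. The last scan day alone called 1035 between the myotubes (3 against 3 cultures), with fewer cultures in the fit, and the first day 0 in Rb-null myoblasts on MOE430A. In wild-type differentiation the last scan day alone gave 1200, with culture B as the only myoblast culture. The spread behind that count came from the myotube cultures alone, so it is no replicated check within the day. Probe sets in place of genes gave 7972, 2623 and 4882 in wild-type differentiation, between the myotubes and between the Rb-deficient states, with more features tested. A fold of at least 2 left 2674 and 1553 in the first and last of these.

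The following changes reversed. Tpm1 (-1.20) and Nip7 (0.24) did so in wild-type differentiation with the mean of all probe sets, and Rbl1 (0.32) with MOE430B first. Myof reversed between the myotubes without a filter (-0.014), Gabarapl2 (0.56) with MOE430B first, and Topbp1 (-0.16) in the difference of the Rb effects with MOE430B first. Each of these settings uses other probe sets for the gene.

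Leaving out 1 culture gave 2814 (without C) to 4926 (without B) genes in wild-type differentiation, 0 to 1 (without D) in Rb-null myoblasts, 1157 to 1727 between the myotubes, 1543 (without D) to 3236 (without B) between the Rb-deficient states, and 138 (without C) to 328 (without K) for the difference of the Rb effects. Counts also moved more than 1.5 times without E, to 1729 between the Rb-deficient states and to 155 for the difference, and without D to 169 for the difference. Lists called ranged over 7 to 9, 5 to 7, 9 to 11, 9 to 12 and 8 to 12. The Rb1 change lay between -2.11 and -1.53 in myoblasts and between -2.21 and -2.02 in myotubes, and 0 genes were shared by both Rb effects. Named genes lost a call in 356 cases, gained one in 10 and reversed in 0. Signals near the offset limit what dim genes can show.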

Other observations

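The following comparison was chosen after the values were seen. Wild-type myotubes against wild-type myoblasts, and MCK-cre Rb-flox myotubes against Rb-null myoblasts, share no arrays. Of the genes called in each, 761 rose in both (199 if independent) and 943 fell in both (204 if independent). Across 14331 genes, which are not independent replicates, the log2 changes correlated at r = 0.679 and rho = 0.660, with a slope of 0.512. Both comparisons are confounded with scan day, and with scan day as a block 2108 and 193 genes were called. 13 genes were called in opposite directions. Lpl fell in the wild-type pair (-1.88, SE 0.36; -1.13 and adjusted p = 0.0893 with scan day as a block) and rose in the Rb-deficient pair (2.81, SE 0.36). Tap2, a peptide transporter subunit, changed by -1.75 (SE 0.23) and 0.96 (SE 0.23), Asf1b, a histone chaperone, by -0.76 (SE 0.18) and 0.65 (SE 0.18), and Ckb, brain creatine kinase, by 1.0 (SE 0.23) and -0.88 (SE 0.23). The others were Smim5, Scpep1, Clmn, Primpol, Pcolce, Plod2, Esyt1, Osgepl1 and Mpp6.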
